A study of Mus musculus with 12 samples.

How the data were processed

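Total RNA of haematopoietic stem cells, sorted by flow cytometry from mouse bone marrow and extracted with Trizol, was measured on 12 Affymetrix arrays, 1 per sample, after labelling as biotinylated cRNA. The 4 groups, each of 3 biological replicates, were wild-type GFP-, wild-type GFPhigh, Nras GFP- and Nras GFPhigh, as the labels name them. The deposited values are intensity, in MAS5 signal units on a linear scale, with MAS5 named per the submitters' processing notes and its version not given in the sources used here. The table holds 45101 probe sets, and the mean of each array without its lowest and highest 2% of probe sets was equal on all arrays, as MAS5 scaling makes it. No detection calls were used here, and replicates were not pooled.

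The signals were taken to log2, with 3 values listed at 0 set to a floor of 0.1, and were not normalized further. After 64 control probe sets were left out, 34945 probe sets had exactly 1 gene symbol, 932 had several and 9160 had none in the annotation used, and the last 2 kinds were left out because they name no single gene. Each of the 18193 genes was represented by its probe set of highest mean log2 signal. Of these, 12083 genes were tested, those whose probe set was above the median of its array in at least 3 arrays. The signals of the arrays and their number set the precision, since arrays give no counts. Chromosome positions were not used here.

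One limma model with a mean for each group was fitted over all 12 samples, with an intensity trend in the prior variance, and gave 7 comparisons: GFPhigh against GFP- in each genotype, Nras against wild-type in each population, their interaction, and the averages over both genotypes and over both populations. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and SE is the standard error from limma after its variance moderation. The same model was used to test 27 gene lists, written before the data were examined, by limma's camera with a preset correlation of 0.01. Their p values were adjusted over 135 tests in the first 5 comparisons and over 54 in the other two. The lists hold 710 entries, 638 of them on the array, and cover the cell cycle, HSC identity and quiescence, signalling, metabolism, stress and markers of other blood and stromal cells. Beside it, camera with an estimated correlation, fry, and single genes adjusted over the list alone were run. A list's median is that of the log2 fold changes of its tested genes. Adjusted p values of limma and camera are two-sided.

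The named genes were fixed by rule before the data were examined: genes past the threshold whose groups did not overlap, up to a fixed number each way, or, where none passed, the 5 of smallest p. To these the rule adds up to 4 members of smallest p from each list discussed, and genes fixed in advance, where tested, among them Nras, Mki67, Ccnd1, Kit, Procr and Dusp6. Symbols without a gene name are counted and left unnamed, except where a small count called for them. Steps were tested on simulated, uncorrelated genes, 200 changed in 5 runs. A G1/S list shift of 0.5 (log2) was called in 100% of 20 runs, with correlated genes untested.

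Alternatives set before the data were examined were array weights, a filter at the 75th percentile or none, median centring, quantile normalization, all probe sets one by one, the mean over the probe sets of a gene, leaving out probe sets that match several transcripts (shared probe sets, suffixes _s_at, _x_at and _a_at), a pseudocount at the 25th percentile (15.5 signal units), a block on replicate number, each array left out in turn, only the groups compared, an adjusted p under 0.1 and no intensity trend. Added after seeing the data were a pseudocount of 100, leaving out 4 arrays of array weight under 0.6 (the uneven arrays), a term for replicate 3, only replicates 1 and 2, and array weights together with quantile normalization or with the pseudocount of 100. Other splits of the samples were drawn within populations or genotypes for the averaged comparisons, and for the interaction the residuals were permuted. The span after a list's median, and the range after an adjusted p, are over its alternatives, camera with an estimated correlation and fry apart. Versions were R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.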

Results

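Gene expression was measured in 12 samples of haematopoietic stem cells (HSCs), the bone marrow cells that sustain all blood lineages, with 3 biological replicates in each of 4 groups. The mice were wild-type or carried an Nras mutation, named oncogenic in the series title. Nras encodes a small GTPase that signals to the ERK kinases. Within each genotype the cells were sorted into a GFP- population, called cycling per the labels, and a GFPhigh population, called quiescent. The mice received doxycycline for 6 weeks and were followed for a further 12 weeks. A GFP label that doxycycline switches on is diluted when cells divide, so cells that divide seldom keep it. The arrays gave signals for 12083 genes that were tested. The median signal of an array lay between 44 and 129.6 intensity units.

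The array weight was 0.522 in wild-type GFPhigh replicate 2, 0.308 in Nras GFP- replicate 1, 0.403 in Nras GFPhigh replicate 1 and 0.503 in Nras GFPhigh replicate 2, against 0.903 to 2.46 in the other 8, and these 4 are called the uneven arrays. The CreX hybridisation spike read 28340.4 and 26505 in Nras GFPhigh replicates 1 and 2, 16055 and 17345 in the other two uneven arrays, and 9325 to 15457 in the other 8. The ratio of the 3' to the 5' Gapdh probe set, higher in degraded RNA, was 7.28 in Nras GFPhigh replicate 1 and 5.7 in Nras GFPhigh replicate 3, against 2.57 to 4.48 in the other 10. Replicate 3 of every group differed from replicates 1 and 2 in sex-linked transcripts. Xist, the transcript that silences an X chromosome in female cells, read 91.8 to 205 in replicate 3 and 5773 to 11481 in replicates 1 and 2. Eif2s3y, a Y-linked gene, read 3877 to 4545 and 2.3 to 675. Medians from only replicates 1 and 2 and from replicate 3 alone therefore stand beside the pooled ones of the called lists.

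**Figure D1:**
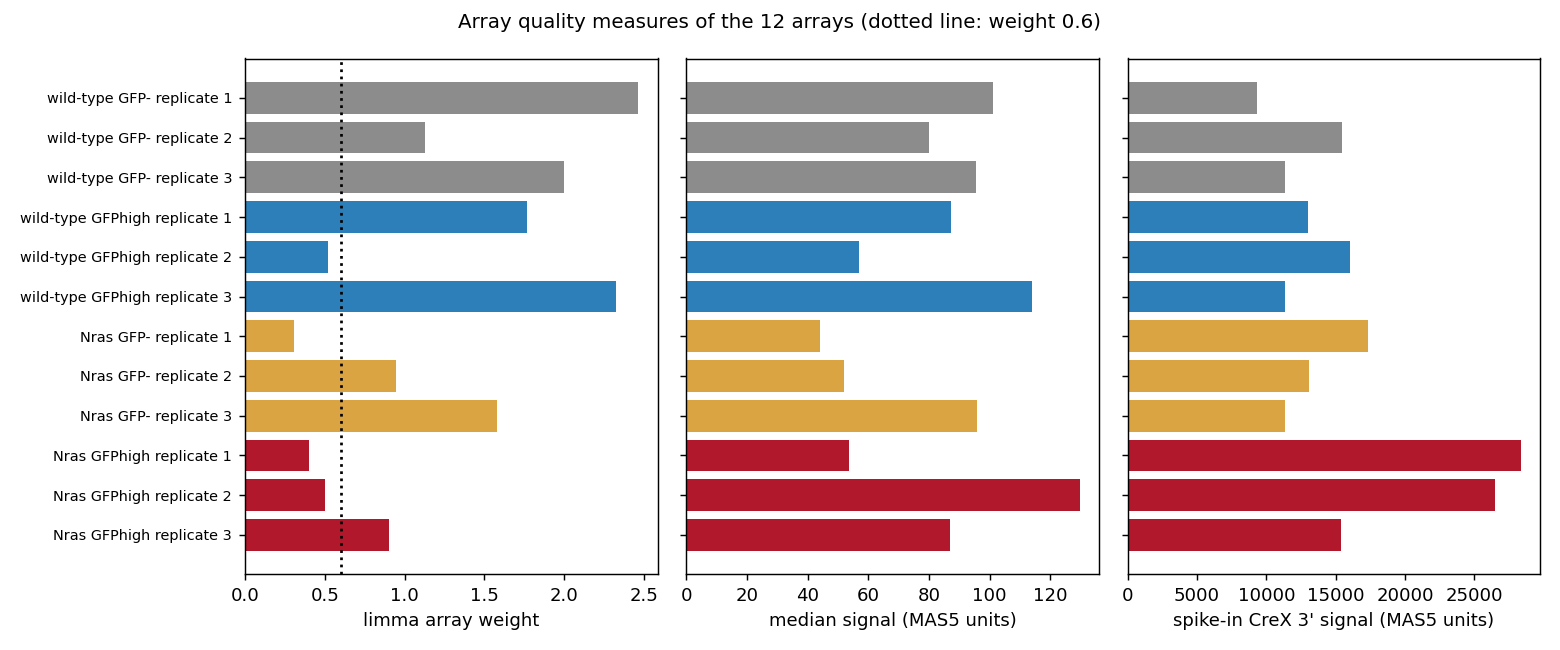
Bars show, for each of the 12 arrays, the array weight from limma, the median signal in intensity units and the signal of the CreX spike. The 4 uneven arrays have weights of 0.308 to 0.522, and Nras GFPhigh replicates 1 and 2 have the highest spike signals.

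The first comparison asked how GFPhigh HSCs differ from GFP- HSCs over both genotypes, with 6 samples on each side. Cell cycle genes fell in GFPhigh cells. Among genes of G1/S and DNA replication 24 of 28 were lower, with a median log2 fold change of -0.99 (-1.32 to -0.72 over the alternatives, as given after other medians), and among genes of G2/M and mitosis 27 of 28 were lower, with a median of -1.45 (-1.66 to -1.01). HSC identity and self-renewal genes rose, 21 of 28 being higher with a median of 0.35 (0.15 to 0.43), and so did HSC quiescence regulators, 18 of 27 being higher with a median of 0.45 (0.28 to 0.55). The adjusted p values from limma's camera were 3.3e-09, 8.35e-09, 0.000117 and 0.00825 in that order, and the adjusted p = 0.13, 0.3, 0.315 and 0.315 with an estimated correlation. The G2/M score, the median deviation of its genes from their mean over all arrays, was 0.68 ± 0.46 in wild-type GFP- and -0.85 ± 1.02 in wild-type GFPhigh cells (SD, n = 3). In Nras cells it was 1.13 ± 0.92 and -0.55 ± 0.99 (SD, n = 3).

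Of the replication genes, Mcm5, a subunit of the replicative helicase, had a log2 fold change of -1.05 ± 0.25 (SE), and Uhrf1, which maintains DNA methylation at replication, -2.65 ± 0.78. Of the mitosis genes, Cdk1, the kinase that drives entry into mitosis, had -1.63 ± 0.53 and Top2a, a DNA topoisomerase, -1.27 ± 0.46. Gfi1, a transcriptional repressor that restrains HSC proliferation, read 4146 and 3993 in wild-type and Nras GFPhigh cells against 789.8 and 286 in GFP- cells, a log2 fold change of 3.10 ± 0.57. Cdkn1c, the cyclin-dependent kinase inhibitor p57, had 2.01 ± 0.49. Mllt3, a regulator of HSC self-renewal, had 0.61 ± 0.11, and Procr, a surface receptor used to sort HSCs, 0.96 ± 0.25. Over the probe sets of a gene the values ran from -3.05 to -1.05 for Mcm5 and -2.65 to -0.23 for Uhrf1. With p values adjusted over the list alone, 5 replication genes, 0 mitosis genes, 6 identity genes and 5 quiescence regulators passed (4 of the last higher and 1 lower), against 0 over all genes.

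Ribosome biogenesis and MYC targets fell, 21 of 30 being lower with a median of -0.27 (-0.61 to -0.18, adjusted p = 0.0013, and adjusted p = 0.321 with an estimated correlation), with Wdr12, a ribosome assembly factor, at -1.11 ± 0.29 (SE), and 2 probe sets from -1.11 to -0.27. Immediate early and dissociation stress genes rose, 21 of 27 being higher with a median of 0.33 (0.16 to 0.58, adjusted p = 0.000133, and adjusted p = 0.324 with an estimated correlation), with the transcription factor Klf6 at 0.79 ± 0.17. p53 targets rose, 14 of 21 being higher with a median of 0.43 (0.11 to 0.64, adjusted p = 0.0167, and adjusted p = 0.3 with an estimated correlation), with Plk2, a polo-like kinase, at 3.25 ± 0.67, and this call ended with no filter or only replicates 1 and 2, adjusted p range 0.00319 to 0.125. Cytoplasmic ribosomal protein genes had a median of 0.30 (-0.031 to 0.38, adjusted p = 1.15e-07, and adjusted p = 0.338 with an estimated correlation), which was -0.031 without shared probe sets. The call ended with quantile normalization (also with weights) or median centring, or without shared probe sets or the uneven arrays, adjusted p range 2.76e-11 to 0.373. Granulocyte markers had a median of 1.02 (0.39 to 2.16, adjusted p = 0.0312, and adjusted p = 0.513 with an estimated correlation), and 0.41 without the uneven arrays. It was -0.76 in wild-type cells (adjusted p = 0.315) and 2.28 in Nras cells. Adjusted over the list alone, 3 ribosome biogenesis genes were lower, and 3 ribosomal protein genes, 1 immediate early gene, 1 p53 target and 0 granulocyte markers were higher.

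No single gene passed: limma called 0 at an adjusted p under 0.05 (8 with array weights). The unadjusted p was under 0.05 in 1072 (527 higher, 545 lower), against 604 by chance in every comparison. The 5 genes of smallest p had adjusted p values of 0.0754 to 0.0786. Ndnf, a secreted glycoprotein, read 2184 and 1482 in wild-type and Nras GFPhigh cells and 35 and 59.5 in GFP- cells (log2 fold change 5.30 ± 0.78, SE). Cyp26b1, which degrades retinoic acid, had 3.87 ± 0.59, Il10ra, a subunit of the interleukin-10 receptor, 4.59 ± 0.65, and Meg3, an imprinted non-coding RNA, 3.43 ± 0.55. H2-Ob, a chaperone of class II antigen presentation, had -5.68 ± 0.89. With low signals on one side the size of a change depends on the floor, and with a pseudocount of 100 it was 3.53 for Ndnf, 1.57 for Il10ra and -2.73 for H2-Ob. Over probe sets it ran from 1.98 to 4.59 for Il10ra and 0.33 to 5.11 for Meg3. Without the uneven arrays 3 genes (Wdr12, Gja1 and Rian) and 7 lists passed, against 0 genes and 9 lists with all arrays. The medians of G1/S, G2/M, identity and quiescence genes were then -0.72, -1.09, 0.33 and 0.43. With only replicates 1 and 2 they were -0.92, -1.23, 0.34 and 0.37, and in replicate 3 alone -0.99, -1.62, 0.30 and 0.28. For ribosome biogenesis, immediate early genes, p53 targets, ribosomal proteins and granulocyte markers they were -0.48, 0.22, 0.32, 0.38 and 2.16, and in replicate 3 alone -0.31, 0.38, 0.49, 0.12 and -0.39. Leaving out Nras GFPhigh replicate 3 gave 16 genes, leaving out Nras GFP- replicate 3 gave 3 (Mrpl52, Rin2 and Kank2) and leaving out wild-type GFP- replicate 2 gave 1 (Ndnf). Of the genes named for these counts, Gja1, Rian, Mrpl52, Rin2 and Kank2 were chosen after their values were seen. The quiescence call ended without Nras GFPhigh replicate 1 (adjusted p = 0.0614), range 0.000226 to 0.0614, and the identity median was 0.15 without Nras GFPhigh replicate 1. The granulocyte call ended with no filter, the 75th percentile filter, array weights, weights after quantile normalization or weights and the pseudocount of 100, or without the uneven arrays, wild-type GFP- replicate 2 (adjusted p = 0.121), wild-type GFPhigh replicate 1 (0.195), Nras GFP- replicate 2 (0.0656), replicate 3 (0.0853), Nras GFPhigh replicate 1 (0.145) or replicate 2 (0.187), range 0.000919 to 0.645. Its median was 1.66 without Nras GFPhigh replicate 3. The immediate early median was 0.50 and 0.20 without wild-type GFP- replicates 1 and 2, 0.50 without wild-type GFPhigh replicate 2, 0.21 without Nras GFP- replicate 3 and 0.17 and 0.56 without Nras GFPhigh replicates 1 and 2, and the p53 median was 0.27 without wild-type GFP- replicate 3, 0.27 and 0.21 without wild-type GFPhigh replicates 1 and 3, 0.11 without Nras GFP- replicate 1 and 0.26 and 0.16 without Nras GFPhigh replicates 1 and 3.

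**Figure D2:**
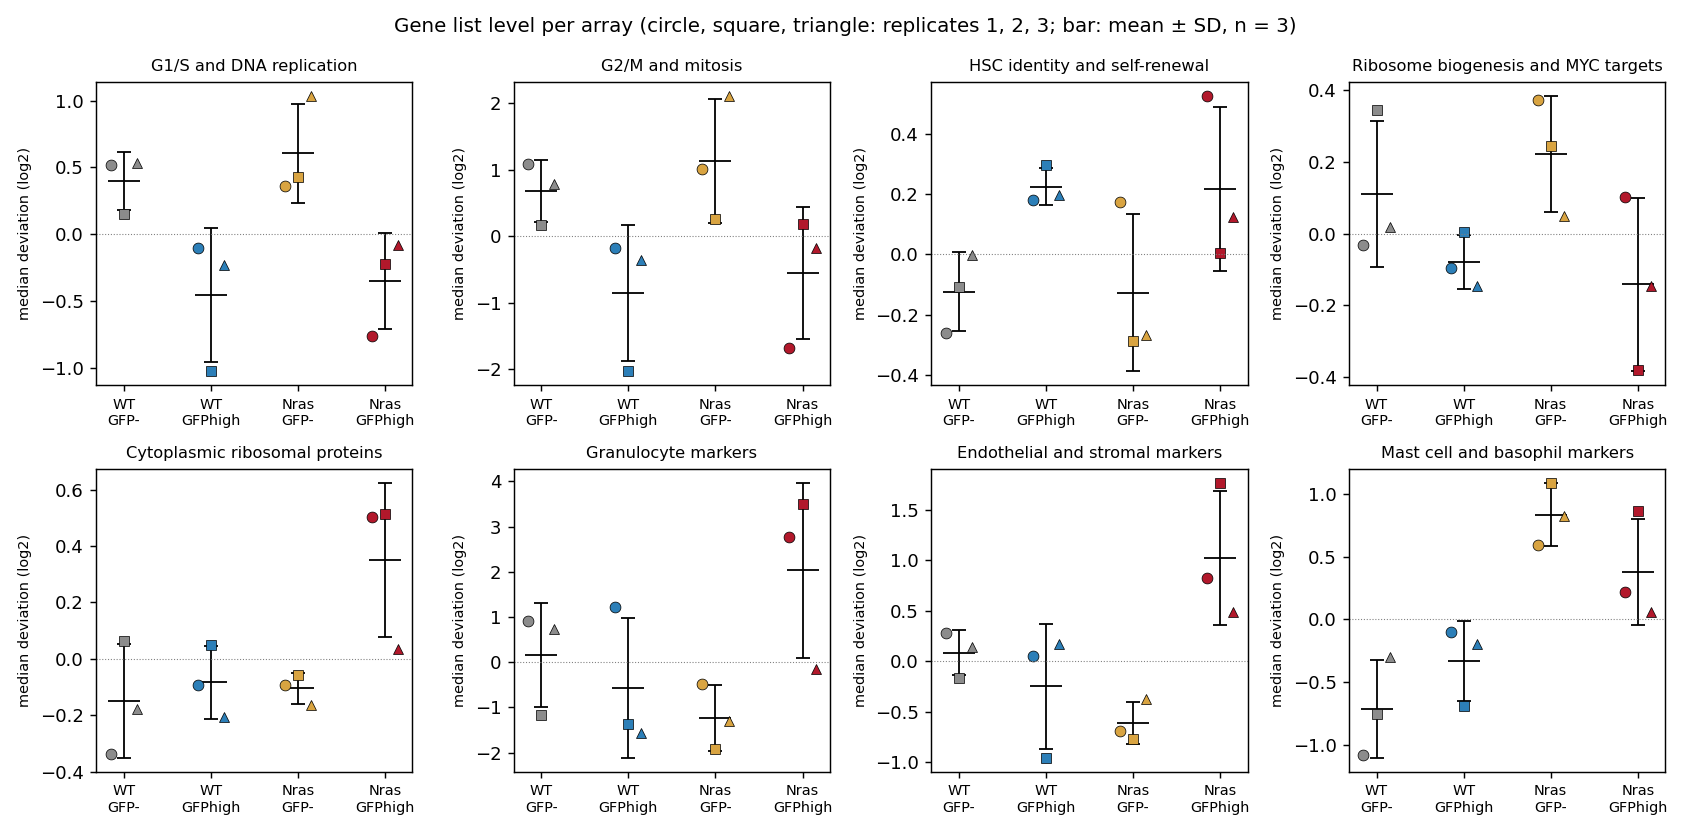
Each panel plots 1 gene list, with the median deviation of its genes (log2) in each array as points and the mean ± SD of each group (n = 3) as bars. The G2/M means are 0.68 and 1.13 in the GFP- groups and -0.85 and -0.55 in the GFPhigh groups.

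In wild-type mice the question was how label-retaining and label-free HSCs differ without the mutation. G2/M and mitosis genes fell in GFPhigh cells, 25 of 28 being lower with a median of -1.65 (-1.89 to -0.70), and so did G1/S and DNA replication genes, 24 of 28 being lower with a median of -0.64 (-0.92 to -0.43). HSC identity genes rose, 22 of 28 being higher with a median of 0.42 (0.31 to 0.57), as did quiescence regulators, 20 of 27 being higher with a median of 0.41 (0.27 to 0.56). Immediate early genes had a median of 0.20 (0.018 to 0.54), with 17 of 27 higher. In that order the adjusted p values were 6.69e-07, 1.54e-06, 5.02e-05, 0.00761 and 0.0344, and the adjusted p = 0.408, 0.327, 0.408, 0.408 and 0.581 with an estimated correlation. Foxo1, a transcription factor that holds HSCs in quiescence, read 1363 against 268 (log2 fold change 2.35 ± 0.76, SE, and 4 probe sets from 0.35 to 2.35), and Cdkn1c 1607 against 326. Birc5, an inhibitor of apoptosis needed for cell division, had -2.71 ± 1.19 and Tk1, a thymidine kinase of S phase, -2.45 ± 0.88. Mki67, a marker of proliferation, had -2.54 ± 1.19, and -0.61 without wild-type GFPhigh replicate 2. With a pseudocount of 100 they were -1.80 for Birc5 and -1.42 for Tk1.

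For single genes in wild-type cells, limma called 0 at an adjusted p under 0.05 and 4 with array weights. The unadjusted p was under 0.05 in 266 (127 higher, 139 lower), against 604 by chance. Adjusted over the list alone, 0 members of the called lists passed. The genes of smallest p were Ntf5, a neurotrophin, at 4.82 ± 0.87 (SE), Ndnf at 5.96 ± 1.10, Meg3 at 4.0 ± 0.78, Tbx1, a T-box transcription factor, at 4.92 ± 1.05 and Lig4, a DNA ligase of end joining, at -8.25 ± 1.78. Values with a pseudocount of 100 were 1.87 for Ntf5, 3.88 for Ndnf, 2.04 for Tbx1 and -1.78 for Lig4. Their adjusted p values were 0.734 or more, and Meg3 had 8 probe sets from -0.51 to 5.99. The array weights calls were Ndnf, Rian (chosen after its values were seen), Ntf5 and Lig4. Leaving the uneven arrays out, 0 genes and 7 lists passed, against 0 and 5, and the G1/S, G2/M, identity, quiescence and immediate early medians were -0.55, -1.08, 0.31, 0.54 and 0.54. From replicates 1 and 2 only, these medians were -0.50, -1.76, 0.42, 0.31 and 0.20, and in replicate 3 alone -0.77, -1.24, 0.23, 0.25 and 0.25. The number of lists was 8 without wild-type GFPhigh replicate 1 or 2, and the G2/M median was -1.08 without wild-type GFPhigh replicate 2. The quiescence call ended with median centring or only replicates 1 and 2, or without shared probe sets or wild-type GFPhigh replicate 3 (adjusted p = 0.15), range 0.000319 to 0.191. The immediate early call ended with quantile normalization (also with weights), median centring, no filter, no trend or only replicates 1 and 2, or without wild-type GFP- replicate 2 (adjusted p = 0.462) or wild-type GFPhigh replicate 3 (0.288), range 0.00387 to 0.462. Its median was 0.42 without wild-type GFP- replicate 3 and 0.54 without wild-type GFPhigh replicate 2.

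The same question was asked within the Nras mutant. Cell cycle genes fell in Nras GFPhigh cells too, with 23 of 28 G1/S genes lower and a median of -0.97 (-1.46 to -0.60), and 25 of 28 G2/M genes lower and a median of -1.53 (-2.01 to -0.82). The adjusted p values were 1.86e-05 and 9.47e-05, and the adjusted p = 0.408 and 0.434 with an estimated correlation. Lig1, the ligase that joins Okazaki fragments, read 228 in Nras GFPhigh cells against 5291 in Nras GFP- cells (log2 fold change -4.53 ± 0.78, SE), and Mcm7, a helicase subunit, had -1.58 ± 0.42, with 4 probe sets from -1.58 to -0.22. Mki67 had -0.21 ± 1.19, and 0.53 with only replicates 1 and 2, and the G2/M median was -1.58, 0.30 and -2.04 between the samples numbered 1, 2 and 3, and -0.82 with probe set means. HSC identity genes rose, 18 of 28 being higher with a median of 0.34 (-0.15 to 0.62), which was -0.15 with median centring (adjusted p = 0.0302, and adjusted p = 0.503 with an estimated correlation). Ifitm1, an interferon-inducible membrane protein, had 1.07 ± 0.18 and Lmo2, a transcriptional cofactor needed to form HSCs, 0.57 ± 0.13. Ribosome biogenesis genes fell, 22 of 30 being lower with a median of -0.41 (-0.90 to -0.26, adjusted p = 0.00708, and adjusted p = 0.477 with an estimated correlation). Once adjusted over the list alone, 2 G1/S genes, 0 G2/M genes and 3 ribosome biogenesis genes were lower and 7 identity genes higher, against 0 over all genes.

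Of the 8 marker lists of other cell types, 3 passed in Nras cells, and of the other 5 that of megakaryocytes had the lowest median, -0.58 (adjusted p = 0.271). Granulocyte markers rose, 15 of 17 being higher with a median of 2.28 (0.43 to 4.38, adjusted p = 0.000582, and adjusted p = 0.434 with an estimated correlation). Ltf, which encodes lactoferrin of neutrophil granules, read 3170 against 14.9. The granulocyte median was 0.43 without the uneven arrays, where the call ended (adjusted p range 9.34e-07 to 0.592). Endothelial and stromal markers rose, 15 of 16 being higher with a median of 1.41 (0.61 to 1.93, adjusted p = 0.00239, and adjusted p = 0.253 with an estimated correlation), and their median was 0.68 without the uneven arrays, where the call ended. Cxcl12, a chemokine of the HSC niche, had a log2 fold change of 5.93 ± 1.07 (SE), and 3.0 with a pseudocount of 100. Monocyte and macrophage markers had a median of 0.86 (-0.047 to 1.31, adjusted p = 0.0344, and adjusted p = 0.503 with an estimated correlation), and -0.047 without the uneven arrays. Adjusted over the list alone, 3 granulocyte, 4 endothelial and 0 monocyte markers were higher. Of the 17 granulocyte markers tested, 4 are held by another list and 5 were above the median gene in wild-type HSCs, against 3 and 4 of the 16 endothelial markers and 1 and 5 of the 10 monocyte markers.

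Cytoplasmic ribosomal protein genes rose in Nras GFPhigh cells, 15 of 17 being higher with a median of 0.49 (-0.016 to 0.68, adjusted p = 2.38e-07, and adjusted p = 0.471 with an estimated correlation), 12 of them when adjusted over the list alone. Their median was 0.16 without the uneven arrays and -0.016 with weights after quantile normalization. The call ended with quantile normalization (also with weights) or median centring, or without shared probe sets or the uneven arrays, adjusted p range 5.99e-11 to 0.483. Oxidative phosphorylation genes had a median of 0.57 (-0.094 to 1.0), with 22 of 28 higher (adjusted p = 0.011, and adjusted p = 0.683 with an estimated correlation), and -0.094 without the uneven arrays. Immediate early genes rose, 23 of 27 being higher with a median of 0.51 (0.021 to 0.84, adjusted p = 0.000864, and adjusted p = 0.477 with an estimated correlation). Adjusted over the list alone, 0 oxidative phosphorylation genes and 1 immediate early gene were higher.

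Among single genes in Nras cells, limma called 0 genes at an adjusted p under 0.05, with 1470 at an unadjusted p under 0.05 (749 higher, 721 lower) and 0 called with array weights. The genes of smallest p, each at an adjusted p of 0.105, were Il10ra at 5.62 ± 0.91 (SE), Cyp26b1 at 4.93 ± 0.84, Ifitm1, Lig1 and B3galt6, a galactosyltransferase, at -5.54 ± 0.90. Il10ra had 2.07 and B3galt6 -3.49 with a pseudocount of 100, and over probe sets 2.48 to 5.62 for Il10ra and -5.54 to -1.85 for B3galt6. Without the uneven arrays 4 genes (Wdr12, and Mtmr4, Mthfd1 and Nrm, chosen after their values were seen) and 5 lists passed, against 0 and 10. The G1/S, G2/M and identity medians were then -0.79, -1.20 and 0.47. With only replicates 1 and 2 the G1/S, G2/M, identity, granulocyte and ribosomal protein medians were -1.0, -1.18, 0.41, 4.38 and 0.62, and in replicate 3 alone -0.85, -2.04, 0.60, 0.49 and 0.25. Those of ribosome biogenesis, immediate early, endothelial, monocyte and oxidative phosphorylation genes were -0.59, 0.40, 1.89, 1.24 and 1.0, and in replicate 3 alone -0.41, 0.47, 1.09, -0.030 and -0.18. Leaving out Nras GFPhigh replicate 3 gave 161 genes, leaving out Nras GFP- replicate 3 gave 12 and leaving out Nras GFPhigh replicate 2 gave 1 (Nrm). The identity call ended with median centring, no filter, no trend or only replicates 1 and 2, or without shared probe sets, Nras GFP- replicate 2 (adjusted p = 0.0792), replicate 3 (0.199), Nras GFPhigh replicate 1 (0.35) or replicate 3 (0.0541), range 0.00059 to 0.437. Its median was 0.52 without Nras GFPhigh replicate 2. The ribosome biogenesis call ended without Nras GFP- replicate 1 (adjusted p = 0.069), Nras GFPhigh replicate 2 (0.0607) or replicate 3 (0.0895), range 2.56e-05 to 0.0895. The oxidative phosphorylation call ended with quantile normalization (also with weights), median centring, no filter, no trend, array weights, probe set means or weights and the pseudocount of 100, or without shared probe sets, the uneven arrays, Nras GFP- replicate 1 (adjusted p = 0.367) or Nras GFPhigh replicate 2 (0.754), range 0.000391 to 0.797. The immediate early call ended with median centring, or without Nras GFP- replicate 3 (adjusted p = 0.0541) or Nras GFPhigh replicate 1 (0.139), range 4.08e-06 to 0.139. Its median was 0.84 without Nras GFP- replicate 1 and 0.77 without Nras GFPhigh replicate 2. The monocyte call ended with median centring, no trend, array weights or weights after quantile normalization, or without shared probe sets, the uneven arrays, Nras GFP- replicate 1 (adjusted p = 0.217), replicate 3 (0.0624), Nras GFPhigh replicate 1 (0.192) or replicate 2 (0.0807), range 0.00423 to 0.962. Its median was 1.31 without Nras GFP- replicate 2. The G1/S median was -0.60 without Nras GFP- replicate 3, the granulocyte median 3.44 without Nras GFP- replicate 1 and 4.14 without Nras GFPhigh replicate 3, and the endothelial median 0.93 without Nras GFP- replicate 1 and 0.93 without Nras GFPhigh replicate 2.

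Across the 12083 genes, which are not independent replicates, the GFPhigh against GFP- log2 fold changes of wild-type and Nras cells had a Pearson r of 0.153 and a Spearman rho of 0.139, with 55.4% of the same sign. The Nras against wild-type ones of GFPhigh and GFP- cells had r = 0.0927 and rho = 0.0901, with 54.3% of the same sign.

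The effect of the mutation over both populations was asked with 6 Nras against 6 wild-type samples. Gem, a small GTPase of the RAD and GEM family, rose in Nras HSCs, 7.67-fold (log2 fold change 2.94 ± 0.38, SE). Its geometric mean signals were 4306 and 4045 in Nras GFP- and GFPhigh cells and 397 and 745 in wild-type GFP- and GFPhigh cells, with all 3 Nras samples above all 3 wild-type samples in either population. Mast cell and basophil markers rose, 8 of 8 being higher with a median of 0.80 (0.37 to 1.22), and immediate early and dissociation stress genes rose, 18 of 27 being higher with a median of 0.35 (0.17 to 0.64). The adjusted p values were 0.000403 and 3.56e-05, and the adjusted p = 0.13 and 0.321 with an estimated correlation. Fcer1a, the alpha chain of the high-affinity IgE receptor, read 0.6 to 1.6 in the 6 wild-type samples and 1.2 to 257.6 in the 6 Nras samples, and its log2 fold change of 5.19 ± 1.41 was 0.91 with a pseudocount of 100, since the wild-type signals lay under the medians of the arrays. Mcpt8, a basophil protease, had 2.08 ± 0.94 and Hdc, which makes histamine, 2.82 ± 1.24, and with that pseudocount 0.53 and 0.88. Of the 8 mast cell markers 2 are held by another list (Gata2 and Itga2b), and 2 (Srgn and Gata2) were above the median gene in wild-type HSCs.

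Cytoplasmic ribosomal protein genes had a median of 0.20 (-0.24 to 0.49) with 14 of 17 higher (adjusted p = 1.15e-07, and adjusted p = 0.338 with an estimated correlation), but -0.068 after quantile normalization. The call ended with quantile normalization (also with weights), or without shared probe sets, adjusted p range 2.76e-11 to 0.872. G2/M genes had a median of 0.41 (0.17 to 0.78) with 20 of 28 higher (adjusted p = 0.0363, and adjusted p = 0.575 with an estimated correlation). Granulocyte markers had a median of 0.76 (-0.44 to 1.67) with 14 of 17 higher, but -0.014 with quantile normalization and array weights (adjusted p = 0.0363, and adjusted p = 0.513 with an estimated correlation), and -0.44 without the uneven arrays. Once adjusted over the list alone, 1 mast cell marker (Fcer1a, with wild-type signals under the medians of the arrays) and 0 members of the other 4 lists passed. Nras itself had a log2 fold change of 0.39 ± 0.26 (SE), Dusp6, a phosphatase that feeds back on ERK, 0.75 ± 0.28, Ccnd1, a G1 cyclin, 0.67 ± 0.24, and Kit, the stem cell factor receptor, -0.12 ± 0.21. None of these 4 passed, and the probe sets differed in sign for Nras (3 probe sets from -0.15 to 0.39), Ccnd1 (3 probe sets from -0.19 to 0.76) and Kit (2 probe sets from -0.12 to 0.022).

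By limma Gem was the 1 gene of 12083 past an adjusted p of 0.05 (adjusted p = 0.0359), and 940 genes had an unadjusted p under 0.05 (321 higher, 619 lower). Gem, read by 1 shared probe set, passed in 12 of the 27 alternatives that kept it. Its adjusted p was 0.00557 to 0.465 and its log2 fold change 2.63 to 3.23. Its call ended with a term for replicate 3 (adjusted p = 0.0902) and with only replicates 1 and 2 (0.465). Among single arrays it ended without wild-type GFP- replicate 1 (adjusted p = 0.096), replicate 3 (0.0531), wild-type GFPhigh replicate 1 (0.156), replicate 2 (0.136), replicate 3 (0.0908), Nras GFP- replicate 1 (0.147), replicate 2 (0.16), Nras GFPhigh replicate 1 (0.0867) or replicate 3 (0.111). Leaving the uneven arrays out, 0 genes and 2 lists passed, against 1 and 5, and the mast cell and immediate early medians were 0.75 and 0.17, the latter no longer past (adjusted p = 0.207, range 2.88e-06 to 0.207). The immediate early call also ended with weights after quantile normalization. With only replicates 1 and 2 these medians were 0.68 and 0.46, and in replicate 3 alone 0.83 and 0.042, and those of ribosomal proteins, G2/M genes and granulocyte markers 0.26, 0.20 and 1.14, and in replicate 3 alone 0.083, 0.83 and -0.23. The number of genes was 5 without Nras GFP- replicate 3 (Gem, Kank2, Prkca, Dock3 and 3110001I22Rik) and 2 without Nras GFPhigh replicate 2 (Gem and Trim13), the genes other than Gem being chosen after their values were seen, and the number of lists 3 without wild-type GFP- replicate 2, wild-type GFPhigh replicate 2 or Nras GFP- replicate 3. The G2/M call ended with no filter, array weights or only replicates 1 and 2, or without shared probe sets, the uneven arrays, wild-type GFP- replicate 2 (adjusted p = 0.168), wild-type GFPhigh replicate 2 (0.106), Nras GFP- replicate 1 (0.0766), replicate 3 (0.26), Nras GFPhigh replicate 2 (0.201) or replicate 3 (0.099), range 0.00182 to 0.336. Its median was 0.62 without wild-type GFPhigh replicate 3, 0.78 without Nras GFP- replicate 2 and 0.72 without Nras GFPhigh replicate 1. The granulocyte call ended with no filter, the 75th percentile filter, array weights, weights after quantile normalization or weights and the pseudocount of 100, or without the uneven arrays, wild-type GFP- replicate 2 (adjusted p = 0.168), wild-type GFPhigh replicate 2 (0.135), replicate 3 (0.129), Nras GFP- replicate 1 (0.0694), replicate 3 (0.0597), Nras GFPhigh replicate 1 (0.18) or replicate 2 (0.225), range 0.000808 to 0.436. Its median was 1.28 without wild-type GFPhigh replicate 1 and 1.67 without Nras GFPhigh replicate 3. The mast cell median was 0.40 without wild-type GFP- replicate 2 and 0.52 without Nras GFP- replicate 2.

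**Figure D3:**
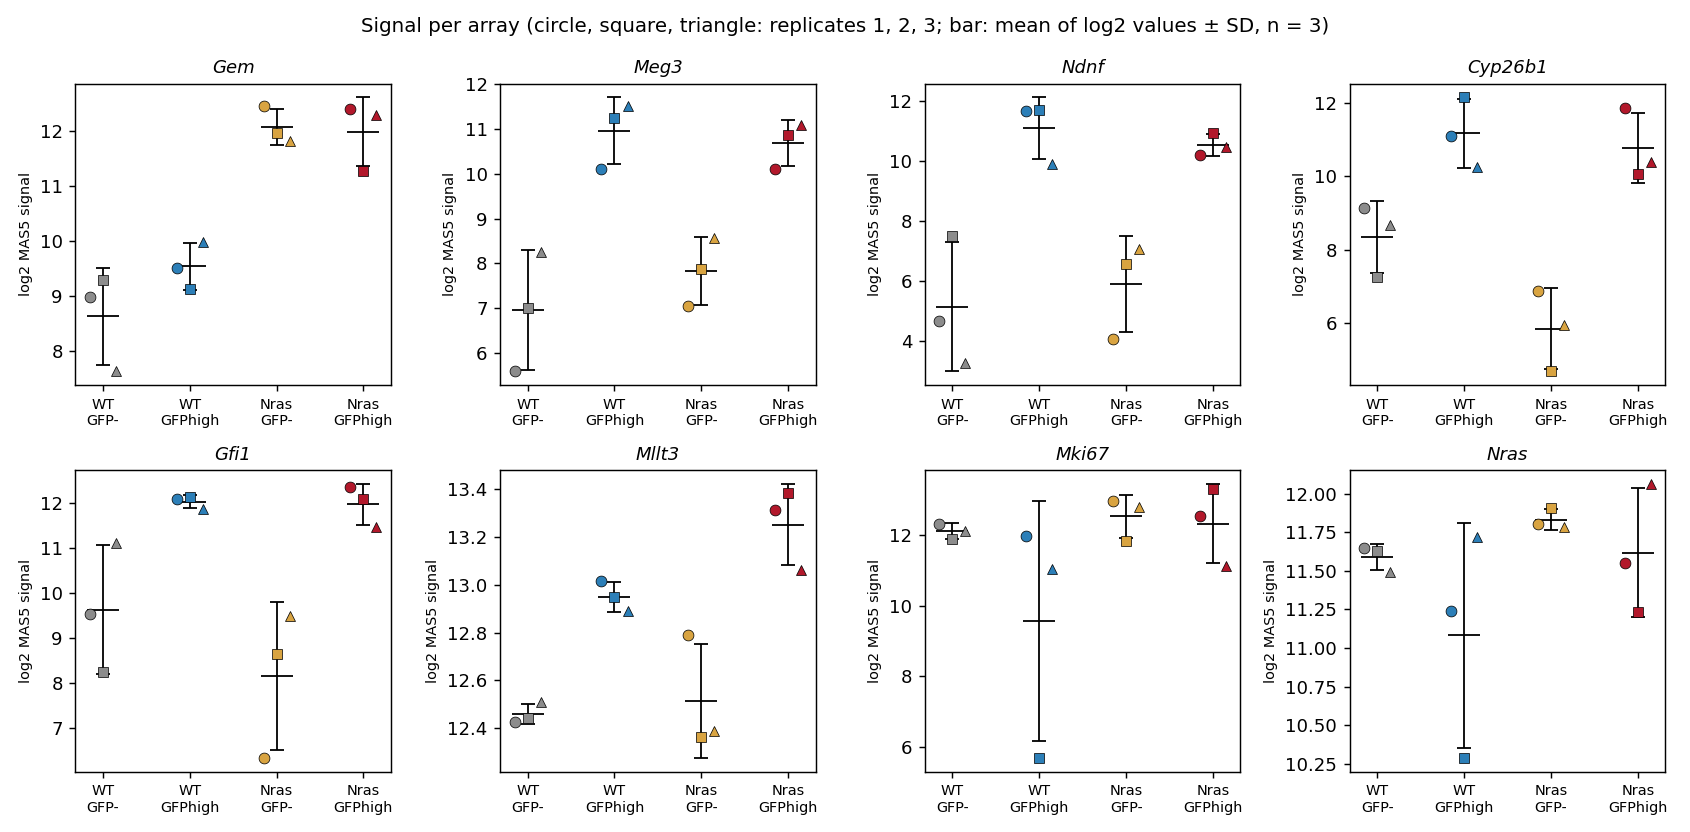
Points show the log2 MAS5 signal of 8 genes in each of the 12 arrays by group. Gem has geometric mean signals of 397 and 745 in the wild-type groups and 4306 and 4045 in the Nras groups.

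In GFPhigh HSCs, called quiescent, the question was what the Nras mutation changes. Cytoplasmic ribosomal protein genes were higher in Nras GFPhigh than in wild-type GFPhigh cells, 15 of 17 with a median of 0.39 (-0.11 to 0.52), though the median was -0.050 after quantile normalization. Immediate early and dissociation stress genes rose, 23 of 27 being higher with a median of 0.52 (0.20 to 0.73). Granulocyte markers (14 of 17 higher, median 2.34, 0.24 to 3.91), endothelial and stromal markers (13 of 16 higher, median 1.0, 0.47 to 1.68) and erythroid markers (14 of 15 higher, median 1.0, -0.66 to 1.84) rose. Oxidative phosphorylation genes had a median of 0.22 (-0.089 to 0.44), with 18 of 28 higher, and -0.0097 after quantile normalization. In that order the adjusted p values were 9.64e-09, 0.000109, 8.6e-05, 0.000864, 0.00578 and 0.0344, and the adjusted p = 0.43, 0.434, 0.408, 0.23, 0.477 and 0.709 with an estimated correlation. Adjusted over the list alone, 9 ribosomal protein, 2 immediate early, 4 granulocyte, 2 endothelial, 0 erythroid and 0 oxidative phosphorylation genes were higher, against 0 over all genes.

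Rpl11, a protein of the large ribosomal subunit, read 13536 in Nras against 8829 in wild-type GFPhigh cells (log2 fold change 0.62 ± 0.17, SE). Camp, an antimicrobial peptide of neutrophil granules, had 3.86 ± 1.24, Ngp, another granule protein, 5.19 ± 1.60, and Sparc, a matrix glycoprotein of stromal cells, 6.13 ± 1.20, and with a pseudocount of 100 Ngp had 3.45, Sparc 2.63 and the granulocyte list a median of 1.23. Sparc had 2 probe sets from 1.65 to 6.13. S100a8, a calcium-binding protein abundant in neutrophils, read 11810.3 and 11840.4 in Nras GFPhigh replicates 1 and 2, which are uneven arrays, and 1750.2 in replicate 3, against 5099, 124 and 147 in wild-type GFPhigh replicates 1, 2 and 3. Without the uneven arrays, which leaves 1 Nras GFPhigh array assumed to vary like the other groups, the granulocyte, endothelial, erythroid, immediate early and ribosomal protein medians were 0.24, 0.47, -0.66, 0.20 and 0.18. Of these 5 calls that of the ribosomal proteins alone remained (adjusted p = 0.0284, range 2.25e-12 to 0.991). It ended with quantile normalization (also with weights), or without shared probe sets, and the endothelial call also with the 75th percentile filter (1.13e-05 to 0.46 over its alternatives). From replicates 1 and 2 only, these medians and that of oxidative phosphorylation were 3.58, 1.59, 1.57, 0.66, 0.48 and 0.32, and in replicate 3 alone 0.69, 0.97, 0.26, 0.14, 0.25 and 0.035.

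For single genes in GFPhigh cells, limma called 0 genes at an adjusted p under 0.05, with 1002 at an unadjusted p under 0.05 (383 higher, 619 lower) and 0 called with array weights. Lig1 had the log2 fold change -3.93 ± 0.78 (SE), Usp27x, a deubiquitinase, -4.80 ± 0.70, Nrm, a nuclear envelope protein, -5.26 ± 1.07, and Zfp53 -5.41 ± 1.11. Nrm had -1.72 and Zfp53 -2.04 with a pseudocount of 100. Their adjusted p values were 0.153 for Usp27x and 0.409 for the others. Nras had 0.53 ± 0.36, with 3 probe sets from -0.75 to 0.53, and Mki67 2.75 ± 1.19 (-0.40 without the uneven arrays), neither past the threshold. Without the uneven arrays 0 genes and 1 list passed, against 0 and 6. Leaving out Nras GFPhigh replicate 3 gave 17 genes and leaving out Nras GFPhigh replicate 2 gave 2 (Nrm, and Trim13, chosen after its values were seen). The oxidative phosphorylation call ended with quantile normalization (also with weights), median centring, no filter, no trend or probe set means, or without shared probe sets, the uneven arrays, wild-type GFPhigh replicate 3 (adjusted p = 0.201) or Nras GFPhigh replicate 2 (0.942), range 0.000836 to 0.962. Its median was 0.44 without Nras GFPhigh replicate 1. The immediate early call also ended with weights after quantile normalization, or without Nras GFPhigh replicate 1 (adjusted p = 0.0785), range 4.94e-06 to 0.119, and the erythroid call with weights after quantile normalization, or without Nras GFPhigh replicate 2 (adjusted p = 0.204), range 0.00034 to 0.877. The erythroid median was 1.68 without wild-type GFPhigh replicate 1 and 1.52 without Nras GFPhigh replicate 3, the granulocyte median 1.05 and 3.91 without Nras GFPhigh replicates 2 and 3, and the endothelial median 1.63 without wild-type GFPhigh replicate 1 and 1.56 and 1.68 without Nras GFPhigh replicates 1 and 3.

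In GFP- HSCs, called cycling, the same mutation was compared. Mast cell and basophil markers rose in Nras GFP- cells, 8 of 8 being higher with a median of 0.55 (0.16 to 1.51, the lowest with no filter). ERK pathway feedback and target genes rose, 14 of 22 being higher with a median of 0.21 (0.0053 to 0.81). The adjusted p values were 0.000622 and 0.0302, and the adjusted p = 0.23 and 0.477 with an estimated correlation. The mast cell score was -0.71 ± 0.39 in wild-type and 0.83 ± 0.25 in Nras GFP- cells (SD, n = 3). Hdc had a log2 fold change of 4.82 ± 1.75 (SE), Mcpt8 2.93 ± 1.33 and Gata2, a transcription factor of mast cells that HSCs also express, 0.81 ± 0.39. Ccnd1 read 3566 against 1599 (1.16 ± 0.34, 3 probe sets from 0.48 to 1.16), and Dusp1, a phosphatase that acts on MAP kinases, 4139 against 1848 (1.16 ± 0.42), while Maff, a small MAF transcription factor in the same list, had -3.05 ± 1.22. The values were 1.62 for Hdc, 0.52 for Mcpt8 and -1.73 for Maff with a pseudocount of 100. G2/M genes had a median of 0.41 (adjusted p = 0.0519) and G1/S genes 0.18 (adjusted p = 0.0996), neither past the threshold, and for the G1/S genes the mean was -0.040.

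For single genes in GFP- cells, limma called 0 at an adjusted p under 0.05 and 0 with array weights. The unadjusted p was under 0.05 in 530 (117 higher, 413 lower), against 604 by chance. Adjusted over the list alone, 0 members of the 2 lists passed. Gem had the smallest p, at 3.44 ± 0.53 (SE) and an adjusted p of 0.262. Dock3, a guanine nucleotide exchange factor, had -6.09 ± 1.03, Acot4, an acyl-CoA thioesterase, -5.20 ± 1.04, Ncam2, an adhesion molecule, -5.61 ± 1.29, with 3 probe sets from -5.61 to -0.52, and Timp3, a metalloproteinase inhibitor, -4.42 ± 0.92, with 4 probe sets from -4.42 to 0.57. The pseudocount of 100 gave -2.0 for Dock3, -1.31 for Acot4, -1.44 for Ncam2 and -1.91 for Timp3. Leaving the uneven arrays out, 0 genes and 1 list passed, against 0 and 2, and the mast cell and ERK medians were 1.51 and 0.11. With only replicates 1 and 2 they were 0.92 and 0.18, and in replicate 3 alone 1.22 and 0.051. Leaving out Nras GFP- replicate 3 gave 8 genes. The number of lists was 4 without wild-type GFP- replicate 1, wild-type GFP- replicate 2 or Nras GFP- replicate 2, 5 without wild-type GFP- replicate 3 and 1 without Nras GFP- replicate 1. The ERK call ended with quantile normalization (also with weights), median centring, no trend, array weights or only replicates 1 and 2, or without the uneven arrays, wild-type GFP- replicate 2 (adjusted p = 0.104), Nras GFP- replicate 1 (0.423) or replicate 3 (0.119), range 0.00207 to 0.499. Its median was 0.39 without wild-type GFP- replicate 3 and 0.53 without Nras GFP- replicate 2. The mast cell median was 1.23 without wild-type GFP- replicate 1 and 1.51 without Nras GFP- replicate 1.

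The interaction asked whether the effect of the mutation differs between GFPhigh and GFP- cells, the bimodal effect named in the series title. The Nras effect was higher in GFPhigh than in GFP- cells for granulocyte markers (13 of 17 higher, median difference 2.75, 0.59 to 5.12), erythroid markers (14 of 15 higher, median 2.14, 0.23 to 2.80) and endothelial markers (14 of 16 higher, median 1.88, 0.74 to 3.29). It was also higher for oxidative phosphorylation genes (22 of 28 higher, median 0.62, -0.036 to 0.89) and for cytoplasmic ribosomal proteins (15 of 17 higher, median 0.39, -0.25 to 0.59), though both medians were below 0 with median centring. The adjusted p values in that order were 0.000172, 0.00892, 0.000713, 0.00708 and 9.05e-05, and the adjusted p = 0.429, 0.477, 0.23, 0.668 and 0.54 with an estimated correlation. G1/S, G2/M and identity genes had medians of -0.027, -0.28 and 0.18 at adjusted p values of 0.327, 0.668 and 0.919, and for the identity genes the mean was -0.061. Ltf had a difference of 9.40 ± 2.31 (SE) and Alas2, the erythroid enzyme of haem synthesis, 4.36 ± 2.39. A pseudocount of 100 gave 6.05 for Ltf and 1.91 for Alas2. Adjusted over the list alone, 3 granulocyte and 2 endothelial markers and 0 members of the other 3 lists were higher.

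For the interaction limma called 0 genes at an adjusted p under 0.05 and 0 with array weights. The unadjusted p was under 0.05 in 566 (294 higher, 272 lower), against 604 by chance. The smallest p values belonged to Usp27x at -6.42 ± 1.0 (SE), Dnpep, an aspartyl aminopeptidase, at -3.0 ± 0.56 with 5 probe sets from -3.0 to 0.78, Sparc at 7.94 ± 1.69 with 2 probe sets from 3.41 to 7.94, Fancb, a Fanconi anaemia protein, at -7.78 ± 1.71 with 2 probe sets from -7.78 to -0.16, and Cd177, a neutrophil surface protein, at 7.69 ± 1.72. With a pseudocount of 100 they were 3.31 for Sparc, -3.52 for Fancb and 2.29 for Cd177. Without the uneven arrays 0 genes and 0 lists passed, against 0 and 5, and the granulocyte, erythroid, endothelial, oxidative phosphorylation and ribosomal protein medians were 0.59, 0.23, 0.74, -0.036 and 0.11. From replicates 1 and 2 only, they were 4.40, 2.80, 3.29, 0.87 and 0.53, and in replicate 3 alone 0.97, 0.20, 1.74, -0.20 and 0.24. Leaving out wild-type GFPhigh replicate 2 gave 1 gene (1810019N24Rik, chosen after its values were seen) and leaving out wild-type GFP- replicate 2 gave 8 lists. The oxidative phosphorylation call also ended with median centring, no filter, no trend, array weights, weights after quantile normalization or weights and the pseudocount of 100, or without shared probe sets, wild-type GFPhigh replicate 3 (adjusted p = 0.0637), Nras GFP- replicate 1 (0.217) or Nras GFPhigh replicate 2 (0.508), range 0.000391 to 0.877, the erythroid call with probe set means or weights after quantile normalization, or without shared probe sets, Nras GFP- replicate 3 (adjusted p = 0.0646) or Nras GFPhigh replicate 2 (0.151), range 0.000789 to 0.962, and the ribosomal protein call with quantile normalization (also with weights), median centring or no trend, or without shared probe sets, adjusted p range 1.13e-08 to 0.988. The erythroid median was 1.26 and 0.96 without wild-type GFP- replicates 1 and 2, 1.41 and 1.07 without wild-type GFPhigh replicates 2 and 3 and 1.23 without Nras GFP- replicate 1, and the ribosomal protein median 0.59 without Nras GFPhigh replicate 3. The endothelial median was 2.85 without Nras GFPhigh replicate 3.

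**Figure D4:**
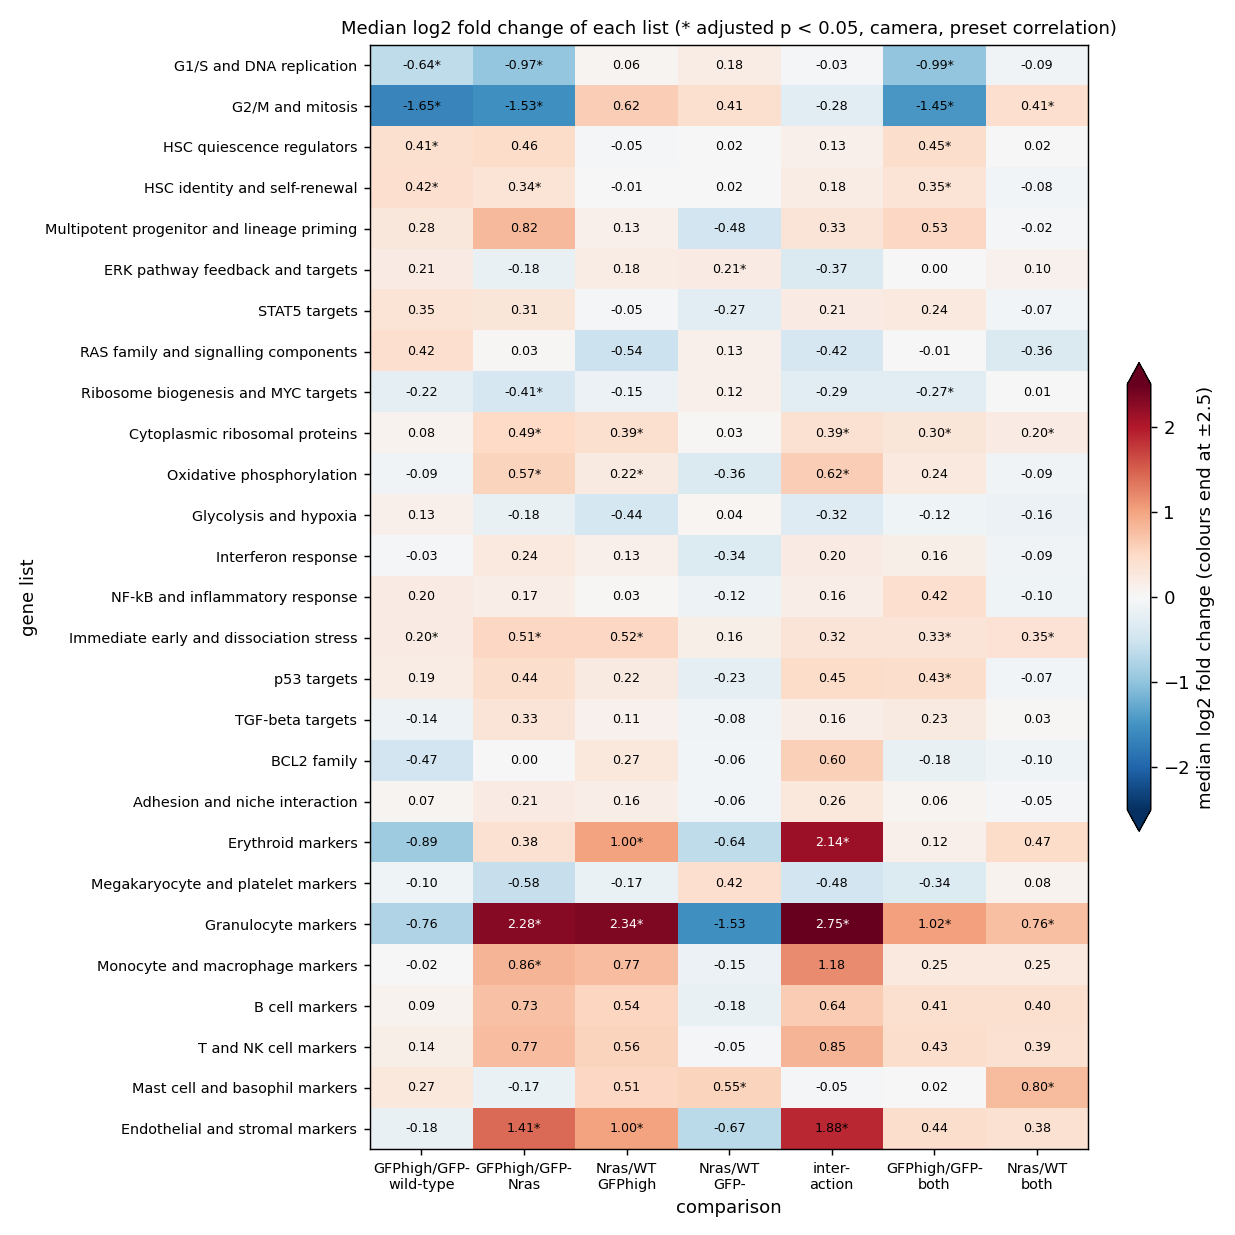
Colours show the median log2 fold change of each of the 27 gene lists in each of the 7 comparisons, with a star where the list passed camera at an adjusted p under 0.05. The granulocyte medians range from -1.53 to 2.75.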

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

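Of the tests in this part, those without the uneven arrays, against matched lists, on the granule genes and on markers of other cell types as a source were chosen only after the results were seen. The effect of the Nras mutation differed between GFPhigh and GFP- cells for 5 gene lists, by camera's test of the interaction with a preset correlation, and for 0 lists with an estimated correlation or without the uneven arrays. The median differences (log2) were 2.75 (granulocyte), 2.14 (erythroid), 1.88 (endothelial), 0.62 (oxidative phosphorylation) and 0.39 (ribosomal protein). Lower scores in Nras GFP- cells add to the first. With an estimated correlation the adjusted p was 0.23 to 0.668. Among 100 permutations, 19 gave as many lists and 55 as many genes at an unadjusted p under 0.05, so chance was not excluded. The real values were 5 lists and 566 genes and the highest others 7 lists and 1622 genes.

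For 9 named genes, all samples of a group lay above those it was compared with in one genotype or population and below them in the other, and limma's interaction test, run on all genes, did not pass for any of them. The differences of the Nras effect (log2) were 9.61 for Ngp, 7.94 for Sparc, 7.69 for Cd177, 6.62 for Cxcl12, 4.91 for Acot4 and 1.57 for Sdhb, a subunit of succinate dehydrogenase. They were -6.42 for Usp27x, -3.0 for Dnpep and -2.12 for Fgd5, a marker of HSCs. How many such genes chance alone gives was not tested.

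Cytoplasmic ribosomal protein genes were higher in Nras GFPhigh than in wild-type GFPhigh cells, with a median of 0.39 (adjusted p = 0.43 with an estimated correlation). MAS5 scaling that raises all bright probe sets may account for this, since the median lay at percentile 96.2 of 10000 lists matched on mean expression and was -0.050 after quantile normalization. The median without the uneven arrays was 0.181 and the call with the preset correlation remained (adjusted p = 0.0284, over a range of 2.25e-12 to 0.991). Whether those arrays are the whole source therefore stays open, because the median shrank and the list still passed. An effect of the genotype also stays open and was not tested apart from these.

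Granulocyte markers were higher in Nras GFPhigh than in wild-type GFPhigh cells, with a median of 2.34. RNA of granulocytes in some samples is a candidate explanation, as 7 granule genes rose and fell together over the 12 samples (median pairwise Spearman correlation 0.804). S100a9, abundant in neutrophils, read 18205 and 1435 in Nras GFPhigh replicates 1 and 3. In wild-type GFPhigh it read 3716 in replicate 1 and 100.2 to 397 in the others. The sort for HSCs would remove granulocytes. The uneven arrays may carry the difference, since without them the median was 0.238. That leaves Nras GFPhigh replicate 3 against wild-type replicates 1 and 3, so array quality cannot be told from replicate number. Granulocyte priming in mutant HSCs stays open and was not tested.

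Cell cycle genes were lower in GFPhigh than in GFP- cells over both genotypes. With camera's estimated correlation the adjusted p was 0.13 for G1/S and 0.3 for G2/M. Of 100 splits, the real one included, 2 gave as many lists and 2 as many genes at an unadjusted p under 0.05. The real counts were 9 lists and 1072 genes, and the highest others 11 and 1257. Such counts over all lists and genes were rare, but chance was not excluded. The splits ignore replicate number and do not test the cell cycle lists by themselves. MAS5 scaling of mid-level probe sets is argued against by the higher of the G1/S and G2/M percentiles among matched lists, which was 0. The uneven arrays are argued against by the medians without them, -0.725 for G1/S and -1.09 for G2/M, both past the threshold at the preset correlation. Cells of another type in the GFP- samples stay open, since the lowest median among 8 marker lists was -0.885 in wild-type cells (erythroid, adjusted p = 0.064, against 0.38 in Nras cells) and -0.584 in Nras cells (megakaryocyte, adjusted p = 0.271), and granulocyte markers had -0.76 and 2.28. A lower rate of cycling in the cells that keep the label also stays open as a hypothesis.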

How the results depend on the processing

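Of the tests here, the alternatives listed at the start as added after seeing the data were chosen only after the results were seen. The others were planned. The G1/S and G2/M lists kept their direction and passed under every alternative run in both genotypes and over both genotypes, camera with an estimated correlation and fry apart. So did the identity list in wild-type cells and over both genotypes, and the ribosome biogenesis and immediate early lists over both genotypes. In Nras against wild-type the mast cell list passed under all 21 settings run in GFP- and all 27 over both populations. The other lists were run under 22 and 28. Over all called lists, 876 alternative values kept the direction of camera's test and the side of the threshold, 232 kept that direction alone and 12 turned in it, and the median changed sign in 20, in 9 of them without a turn of the test. Of the named genes' values 6811 kept sign and side of the threshold, 196 changed sign, 71 passed newly and 15 no longer passed, and 76 of 287 gene and comparison pairs turned at least once. Probe sets of both signs were present in 53 of the 139 pairs with several probe sets.

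Sample number, signal and the size of a change limit what single genes can show. With 200 genes changed in simulated data, 0.3% were recovered at a log2 change of 1 with 3 samples a side and 3.3% with 6, and 55.5% and 85.3% at a log2 change of 4. Of the changed genes with mean signals above the 75th percentile of all genes these shares were 1.11%, 14%, 96.9% and 100%. Scaling moved the median of all genes. With median centring it was 0.12, -0.41, -0.12, 0.43, -0.53, -0.15 and 0.13 (log2), and with quantile normalization -0.011, -0.065, -0.10, -0.032, -0.070, -0.034 and -0.091. As reported it was -0.031, 0.082, -0.090, -0.17, 0.11, 0.018 and -0.15. The order is GFPhigh against GFP- in wild-type and in Nras, Nras against wild-type in GFPhigh and in GFP-, the interaction, and the comparisons over both genotypes and over both populations. Below, values in wild-type or Nras cells and over both genotypes are for GFPhigh against GFP-, and values in GFPhigh or GFP- cells and over both populations for Nras against wild-type. Where leaving arrays out leaves a group with 1 array, that array is assumed to vary like the other groups. For each value below that moved or turned, the cause was not tested, apart from the smaller number of arrays where arrays were left out.

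The number of genes past the threshold moved as follows. The comparison in wild-type cells called 0 as reported, 3 with quantile normalization and array weights, 4 with array weights and 6 with a pseudocount of 100 and array weights. The comparison in Nras cells called 0 as reported, 1 with quantile normalization and array weights, 3 with median centring and 4 without the uneven arrays. Leaving out 1 array at a time gave 0 to 161. The comparison in GFPhigh cells called 0 as reported and 0 to 17 with 1 array left out. The comparison in GFP- cells called 0 as reported, 1 with a pseudocount of 100 and array weights and 2 with quantile normalization and array weights. Leaving out 1 array at a time gave 0 to 8. The interaction called 0 as reported and 0 to 1 with 1 array left out. The comparison over both genotypes called 0 as reported, 1 with no filter on dim probe sets or with no intensity trend, 2 with median centring, 3 without the uneven arrays, 4 with a pseudocount at the 25th percentile, 5 at an adjusted p under 0.1, 6 with a pseudocount of 100, 8 with array weights or with a pseudocount of 100 and array weights and 12 with quantile normalization and array weights. Leaving out 1 array at a time gave 0 to 16. The comparison over both populations called 1 as reported. It called 0 with median centring, no trend, all probe sets one by one, a term for replicate 3 or only replicates 1 and 2. It called 2 with quantile normalization, with or without array weights, and 0 without shared probe sets, which drops Gem. Leaving out 1 array at a time gave 0 to 5.

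The number of gene lists past the threshold moved too. The comparison in wild-type cells called 5 as reported, 0 with camera and an estimated correlation or with fry and 8 with array weights or with a pseudocount of 100 and array weights. The range was 4 to 8 with each array left out in turn. The comparison in Nras cells called 10 as reported, 0 with camera and an estimated correlation or with fry and 5 with median centring or without the uneven arrays. The comparison in GFPhigh cells called 6 as reported, 0 with camera and an estimated correlation or with fry, 1 without the uneven arrays and 3 with quantile normalization and array weights. The comparison in GFP- cells called 2 as reported, 0 with camera and an estimated correlation or with fry, 1 with no intensity trend, without the uneven arrays or with quantile normalization and array weights, 4 with array weights, without shared probe sets, with a pseudocount of 100 or with a pseudocount of 100 and array weights, 5 with the mean over the probe sets of a gene and 6 with the filter at the 75th percentile. Leaving out 1 array at a time gave 1 to 5. The interaction called 5 as reported, 0 without the uneven arrays, with camera and an estimated correlation or with fry, 2 with quantile normalization and array weights and 3 with median centring, with no intensity trend or without shared probe sets. The range was 4 to 8 with each array left out in turn. The comparison over both genotypes called 9 as reported, 0 with camera and an estimated correlation and 1 with fry. The comparison over both populations called 5 as reported, 0 with camera and an estimated correlation, 1 with fry, 2 without the uneven arrays, 3 with no filter on dim probe sets, with the filter at the 75th percentile, with array weights or with quantile normalization and array weights and 11 with the mean over the probe sets of a gene. The range was 3 to 7 with each array left out in turn.

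Lists that were called as reported turned in the direction of camera's test in these settings. The median without the uneven arrays was -0.094 and -0.036 for oxidative phosphorylation in Nras cells and in the interaction, -0.047 for monocyte and macrophage markers in Nras cells, -0.66 for erythroid markers in GFPhigh cells and 0.24 and -0.44 for granulocyte markers in GFPhigh cells and over both populations. For cytoplasmic ribosomal proteins the median was -0.050 and -0.068 with quantile normalization in GFPhigh cells and over both populations. It was -0.25 with median centring in the interaction. Over both populations it was -0.24 without shared probe sets and -0.032 with quantile normalization and array weights. For oxidative phosphorylation in GFPhigh cells it ranged from -0.089 to 0.44 with 1 array left out.

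The correlation across genes between genotypes (the GFPhigh against GFP- changes) was 0.153 as reported, 0.106 with no filter on dim probe sets, 0.186 with array weights, 0.169 with the mean over the probe sets of a gene, 0.134 without shared probe sets, 0.095 with only replicates 1 and 2, 0.196 with quantile normalization and array weights and 0.209 with a pseudocount of 100 and array weights. With 1 array left out it ran from 0.112 to 0.165. The correlation across genes between populations (the Nras against wild-type changes) was 0.0927 as reported, 0.0621 without the uneven arrays and 0.0614 with only replicates 1 and 2. With 1 array left out it ran from 0.0284 to 0.132.

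Single genes whose log2 fold change turned are given here with their value in the setting that turned it. With quantile normalization, Tpx2 had 0.76 and Npm1 -0.10 in Nras cells, and Rps14 had -0.10, Atp5a1 -0.072, Dnajb1 -0.094, Car2 -0.070, Kit -0.012 and Procr -0.052 in GFPhigh cells. Cdkn1a had 0.44 in GFP- cells, and Cd48 had 0.079 over both populations. With median centring, Stat5b had 0.024 in wild-type cells, and Npm1 had -0.016, Kit -0.32 and Cish -0.22 in Nras cells. Cdkn1a had 0.41, Kit 0.32 and Stat5a 0.45 in GFP- cells, and Rps14 had -0.10, Rps15 -0.13, Rps18 -0.17, Nras -0.35, Kit -0.31 and Dusp6 -0.22 in the interaction. Ccnd1 had -0.16, Kit -0.17 and Spry2 -0.11 over both genotypes, and Kit had 0.16, Cd48 0.27, Procr 0.056 and Stat5b 0.056 over both populations. With quantile normalization and array weights, Npm1 had -0.094, Cd48 -0.22, Dusp6 0.035 and Cish -0.27 in Nras cells, and Rps14 had -0.10, Atp5a1 -0.10, Hspa8 -0.0017, Dnajb1 -0.082, Car2 -0.021 and Cdkn1c 0.29 in GFPhigh cells. Cdkn1a had 1.13, Spry2 -0.060 and Cish 0.071 in GFP- cells, and Rps18 had -0.016 and Cdkn1a -0.20 in the interaction. Kit had -0.0070 over both genotypes, and Rps3 had -0.0022, Hspa8 -0.0020 and Cd48 0.13 over both populations. With array weights, Cd48 had -0.69 and Cish -0.079 in Nras cells, and Cdkn1c had 0.25 in GFPhigh cells. Cdkn1a had 0.88 and Spry2 -0.10 in GFP- cells, and Cdkn1a had -0.0044 in the interaction. Kit had -0.028 and Spry2 -0.015 over both genotypes, and Cd48 had 0.42 over both populations. With a pseudocount at the 25th percentile, Cd48 had 0.39 over both populations.

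Changes of the floor, the probe sets and the arrays used turned others. With a pseudocount of 100, Cdkn1a had 0.24 in GFP- cells, and Cd48 had 0.35 over both populations. With a pseudocount of 100 and array weights, Cd48 had -0.59 and Cish -0.0090 in Nras cells, and Cdkn1c had 0.20 in GFPhigh cells. Cdkn1a had 0.90, Cd48 0.20 and Spry2 -0.053 in GFP- cells, and Cdkn1a had -0.0072 in the interaction. Kit had -0.010, Slamf1 0.026 and Spry2 -0.014 over both genotypes, and Cd48 had 0.42 over both populations. With the mean over the probe sets of a gene, Rb1 had 0.31 in wild-type cells, and Ccnd1 had -0.043 in GFPhigh cells. Slamf1 had -0.20 in GFP- cells, and Rps18 had -0.17 and Nras -0.30 in the interaction. Ccng1 had -0.088, Ccnd1 -0.032, Kit -0.011 and Slamf1 0.34 over both genotypes, and Cdkn1a had -0.23, Spry2 0.20 and Stat5b 0.010 over both populations. Without shared probe sets, Slamf1 had -0.48 in wild-type cells, and Rps18 had -0.16, Cox5b -0.073 and Slamf1 4.55 in Nras cells. Rps18 had -0.55, Cycs -0.94, Tfrc -0.17 and Slamf1 1.96 in GFPhigh cells, and Slamf1 had -3.08 in GFP- cells. Dnpep had 0.78, Rps18 -0.26, Cycs -0.60, Cox5b -0.017, Nras -0.0033 and Slamf1 5.04 in the interaction, and Rps18 had -0.031 and Slamf1 2.04 over both genotypes. Rps18 had -0.42 and Rps3 -0.35 over both populations. Without the uneven arrays, Cox5b had -0.020, Lyz1 -0.066, Nras 0.21, Cd48 -2.71 and Dusp6 0.39 in Nras cells, and Slc4a1 had -1.49, Alas2 -0.86, Tfrc -0.40, Col3a1 -0.12, Mki67 -0.40, Ccnd1 -0.059, Cdkn1c 0.76 and Cd48 -0.82 in GFPhigh cells. Cdkn1a had 0.65, Spry2 -0.28, Stat5b -0.070 and Cish 0.33 in GFP- cells, and Mki67 had -0.60 and Cdkn1a -0.19 in the interaction. Nras had 0.052 and Slamf1 0.29 over both genotypes, and Mmp9 had -0.29 and Mki67 -0.10 over both populations. With only replicates 1 and 2, Mki67 had 0.53 in Nras cells, and Cdkn1c had -0.30 in GFP- cells. Ccnd1 had -0.093 and Cd48 1.65 over both genotypes, and Cdkn1a had -0.022 and Cdkn1c -0.56 over both populations.

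With 1 array left out at a time, the log2 fold changes of these genes spanned 0 or turned. Stat5b ran from -0.43 to 0.36 in wild-type cells. Mki67 ran from -0.70 to 0.40, Kit from -0.059 to 0.41, Cd48 from -0.13 to 3.98 and Cish from -0.85 to 1.43 in Nras cells. Ccnd1 ran from -0.053 to 0.43, Cdkn1c from -0.53 to 0.18, Kit from -0.18 to 0.29 and Procr from -0.12 to 0.53 in GFPhigh cells. Cdkn1a ran from -1.76 to 0.65, Cdkn1c from -0.056 to 0.93, Spry2 from -0.28 to 0.55, Stat5b from -0.070 to 0.95 and Cish from -1.42 to 0.33 in GFP- cells. Nras ran from -0.11 to 0.61 and Cish from -2.20 to 0.077 in the interaction. Ccnd1 ran from -0.11 to 0.13, Kit from -0.11 to 0.12, Slamf1 from -0.58 to 0.21, Cd48 from -1.27 to 0.79 and Spry2 from -0.19 to 0.23 over both genotypes. Cdkn1a ran from -0.20 to 1.12, Cdkn1c from -0.12 to 0.37, Slamf1 from -0.66 to 0.12, Cd48 from -1.22 to 0.77 and Stat5b from -0.50 to 0.013 over both populations.

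The replicate numbers are not stated to pair the samples, so a block on replicate number was run only as a check. Residuals of samples with the same number in different groups had correlations of -0.0444 to 0.152 over 18 pairs, 3 of them above 0.1, and 9 of 12 samples correlated best with their own number. With the replicate block limma called 0 genes in each of the 7 comparisons, 1 fewer (Gem) than reported for Nras against wild-type over both populations, and the number of lists was 6, 10, 6, 4, 5, 9 and 5, in the order given for scaling. Blocking takes degrees of freedom from the 12 samples, and whether this or the block itself moved the counts was not tested.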

Other observations

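In this part the test of imprinted genes and the counts with a term for replicate 3 or only replicates 1 and 2 were chosen only after the results were seen. RAS family and signalling components had a median of 0.42 in GFPhigh against GFP- wild-type cells, with 17 of 21 genes higher, and did not pass (adjusted p = 0.0862). STAT5 targets, which answer to cytokine receptors, had 0.35 in the same comparison, 14 of 20 being higher (adjusted p = 0.102). Genes of glycolysis and hypoxia had a median interaction of -0.32, 19 of 25 being lower (adjusted p = 0.0911). B cell markers had 0.40 in Nras against wild-type over both populations (adjusted p = 0.0586), and T and NK cell markers had 0.56 in Nras against wild-type GFPhigh cells (adjusted p = 0.126). Megakaryocyte and platelet markers had 0.42 in Nras against wild-type GFP- cells (adjusted p = 0.107).

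Other lists passed in no comparison, and each is given where its p was smallest. Genes of multipotent progenitors and lineage priming had a median of 0.53 in GFPhigh against GFP- over both genotypes (adjusted p = 0.497). In GFPhigh against GFP- in Nras interferon response genes had 0.24 (adjusted p = 0.168). NF-kB and inflammatory response genes had a median of 0.42 in GFPhigh against GFP- over both genotypes (adjusted p = 0.231). In Nras against wild-type in GFPhigh TGF-beta targets had 0.11 (adjusted p = 0.488). BCL2 family genes, which control apoptosis, had a median of -0.47 in GFPhigh against GFP- in wild-type (adjusted p = 0.193). In Nras against wild-type over both populations adhesion and niche interaction genes had -0.048, with a mean of 0.058 (adjusted p = 0.146). The median, the mean and the direction of the test differed in sign in 45 of 189 list and comparison pairs, 0 of them called.

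Imprinted genes drew attention in GFPhigh against GFP- cells over both genotypes. Meg3 had a log2 fold change of 3.43, Rian 4.63, Peg3 4.80, Ndn 1.06, and Cdkn1c 2.01, of which Rian, Peg3 and Ndn were chosen after their values were seen. None passed in limma at an adjusted p under 0.05. A shift of imprinted genes as a class could underlie this, and was tested on 24 other imprinted genes of 36 listed. Of these 17 were higher and 7 lower, with a median of 0.28, and the camera p of 0.0782 does not decide it, against a bound revised after that value was seen.

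With 3 samples a side there are 10 splits, too few for a share under 0.05. The real and the highest other number of genes at an unadjusted p under 0.05 were 266 and 353 for GFPhigh against GFP- in wild-type, 1470 and 1554 in Nras, 1002 and 1142 for Nras against wild-type in GFPhigh and 530 and 751 in GFP-. For lists they were 5 and 5, 10 and 10, 6 and 7, and 2 and 7. For Nras against wild-type over both populations, 3 of 100 splits gave as many genes past the threshold (real 1, highest other 2). At an unadjusted p under 0.05, 3 gave as many (real 940, highest other 1097). Such counts were rare, but chance was not excluded. These splits ignore replicate number, and 0 genes passed with a term for replicate 3 or only replicates 1 and 2. For lists, 34 splits gave as many (real 5, highest other 10), so chance was not excluded.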
